A study of Phaeodactylum tricornutum with 15 samples.

How the data were processed

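RNA of Phaeodactylum tricornutum was measured in 15 libraries made with the TruSeq RNA v2 kit from 1 ug of RNA and read as single ends of 100 bp on an Illumina HiSeq instrument. Cultures of strain UTEX 646 (WT) and of the antisense lines Na1 and Ta3 were grown for 4 days at 18 C in cycles of 16 h light (40 umol photons per square metre and second) and 8 h darkness. They were then kept in darkness for 72 h and sampled, or given 1 h of blue light of 465 nm (10 umol photons per square metre and second) before sampling. Groups and replicate numbers were taken from the labels, and all 15 libraries were used. The deposited columns of the lines are headed Nad and Tad. They were matched to Na1 and Ta3 by their opening letters, replicate number and light condition.

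The deposited table holds 12298 gene models. Per the file headers it gives raw counts, TPM (transcript levels scaled by length) and RPKM columns for each library. The counts in the deposited columns are whole numbers, and these were the only values used for the tests. The deposited TPM values followed from the counts and the model length to within a relative difference of 5.3e-15. The log2 fold changes of 7 comparisons were computed by the authors, and their sign was read from the values as blue light over darkness and line over WT. The q-values beside them were also computed by the authors and are read here as adjusted p-values. The other deposited column is the length of each gene model in bases, and 90% of the lengths are multiples of 3. CASAVA 1.8 and edgeR (no version) are named in the submitters' notes, and the aligner, the counting tool and the genome build are not given in the sources used here. The RPKM columns were not used, because the counts hold the same measurement.

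Symbols came from a RefSeq table joined by locus tag, which matched 9081 models and gave 566 of them a symbol, 562 of which were tested. The table holds no descriptions, so functions stated beside a symbol are general knowledge of the gene name and were not tested here. The joined tables name no gene CryP, and the model CPF2, of the cryptochrome and photolyase family, was taken for it by a rule set before the data were examined. No source used here states that identity.

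Counts were normalised by TMM factors, which ran from 0.78 to 0.954 in darkness and from 1.042 to 1.249 after blue light. Models were kept by filterByExpr on the 6 groups (11119 kept), and a model with 1 mean per group was fitted to all 15 libraries with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Comparisons were contrasts tested by edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 2 lines were compared with WT in each condition, the light response was tested in each strain, and the difference between light responses was tested as an interaction. Groups of 2 libraries share their estimate of the spread with all groups. Errors of log2 fold changes are the edgeR estimates divided by the square root of F, and CPM (counts scaled to library size and TMM factor by edgeR) are given as mean and SD. Principal components were drawn from log2 CPM with matplotlib 3.10.9. The step was tested on simulated data with 200 changed genes and 10919 unchanged ones, before the filter left 11011 and 11009 genes. At 2-fold it found 77 of 100 in the contrast of WT light and 61 of 100 in that of Na1 in darkness. At 4-fold it found 92 and 93 of 100, with 12 and 4 false calls. In the real data 76.17% of tested genes were called in WT light, and the simulation did not cover a response of that extent or its scaling.

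Named genes followed a rule set before the data were examined. It took the 8 highest and 8 lowest log2 fold changes among called genes that have a symbol, at least 10 CPM in 1 group and complete separation of the libraries of both groups. It added the top 2 per direction without a symbol, up to 4 genes with the smallest adjusted p per gene list discussed (2 where none passed), the gene taken for CryP, and every photoreceptor, photolyase and Lhcx gene. Interactions were ranked in the same way, and genes shared by both lines by the smaller of the 2 changes. Not every gene the rule took is printed, chiefly those without a symbol. Genes with at most 3 reads over all libraries of a group are given as CPM levels without a fold change. Pt-KIF6 in the light responses of the 3 strains was added after its values were seen.

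The gene lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. Their first wording matched descriptions. It was rewritten by symbol once the table was seen to hold none, before any test. Of 36 lists 33 had at least 3 measured genes. They cover antenna proteins (Lhcf, Lhcr, Lhcx, and all light-harvesting proteins), tetrapyrroles, carotenoids, photosystem and electron transport, Calvin cycle, photorespiration, photoreceptors and photolyases, glycolysis, pyruvate dehydrogenase and TCA cycle, fatty acid synthesis, fatty acid activation, ribosomal proteins, diatom-specific and conserved cyclins, cyclin-dependent kinases, the anaphase-promoting complex, kinesins, DNA replication, histones, heat shock factors, chaperones, redox genes, DNA repair, the proteasome, the COP9 signalosome, ubiquitin ligation, nitrogen assimilation, iron uptake, plastid translocators and vesicle coats, and the untested isoprenoid synthesis, aminoacyl-tRNA synthetases and noncoding models.

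Alternatives were RLE factors, library sizes alone, no filter (at least 1 read), a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, a fit of the groups compared alone, the replicate number as a block, a 2-fold threshold, and leaving out each of the 15 libraries. After the data were seen, 2 more were added. One left out 3 blue-light libraries, 1 of each strain, and the other gave them a term in the model. Of the 18 choices of 1 blue-light library per strain, theirs had the highest mean correlation of deviations. Overlap of the 2 lines was set beside 20 simulations of unchanged lines that share the WT libraries. Libraries within a group were checked against each other for duplicates by the chi-square of their counts, and none were duplicates. The chi-square per degree of freedom was lowest for WT blue-light replicates 2 and 3 (3.35) and Na1 blue-light replicates 1 and 2 (5.52). For the other pairs of these groups it was 38.5 to 49.7. Whether the close pairs came from separate cultures rests on the labels alone.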

Results

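RNA was sequenced from the diatom Phaeodactylum tricornutum in 15 libraries that fall into 6 groups. The strains were the wild type (WT, strain UTEX 646) and 2 antisense lines, Na1 and Ta3, which carry an antisense construct against the plant-like cryptochrome CryP, a blue-light receptor. Cultures were sampled after 72 h of darkness, or after the same darkness followed by 1 h of blue light. There were 3 libraries each of WT in darkness, WT after blue light and Na1 after blue light, and 2 libraries each of Na1 in darkness, Ta3 in darkness and Ta3 after blue light. Per the labels these are biological replicates, and if so the errors and p-values below measure the spread between cultures. WT blue-light replicates 2 and 3, and Na1 blue-light replicates 1 and 2, were closer in their counts than the other pairs of their groups. Library totals ran from 9473017 to 12272288 counts, and 11119 of 12298 gene models were tested. Principal component 1 held 80.6% of the variance and separated dark from blue-light libraries in every strain, and component 2 (8.05%) separated the strains. Log2 CPM correlated across genes at 0.969 to 0.995 within groups and at 0.535 to 0.756 between dark and blue-light libraries (genes are not independent replicates). The 10 most abundant gene models took 7.41 ± 0.64% (SD, n = 3) of WT counts in darkness and 3.19 ± 0.11% (n = 3) after blue light.

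**Figure D1:**
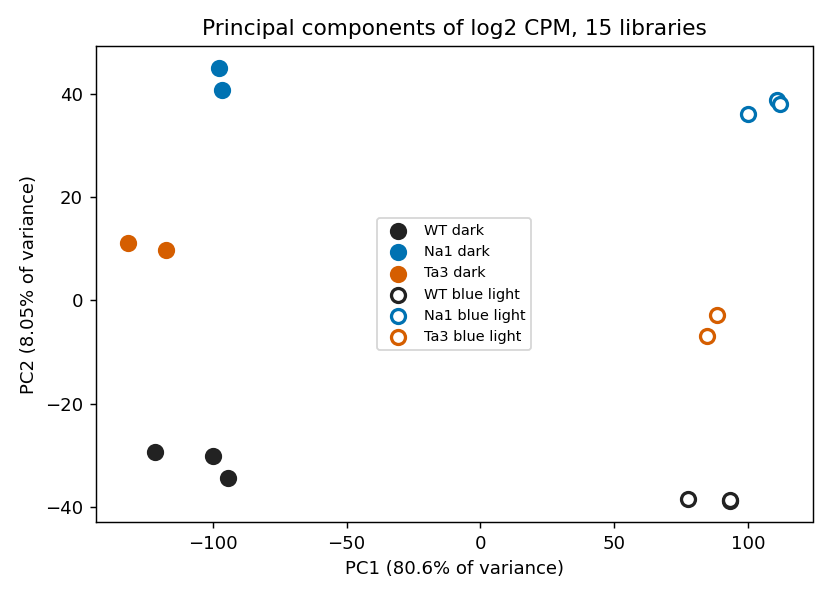
Principal components 1 (80.6% of variance) and 2 (8.05%) of log2 CPM, with 1 point per library, filled for darkness and open for blue light, coloured by strain. Dark libraries lie between -131.6 and -94.4 on component 1 and blue-light libraries between 77.5 and 112.

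The gene model taken for CryP before the data were examined, CPF2 (Phatr3_J34592), a member of the cryptochrome and photolyase family, was measured in every library. In darkness its normalised level was 11.4, 5.13 and 10.3 CPM in the 3 WT libraries, 10.6 and 11.1 in the 2 Na1 libraries and 5.29 and 7.25 in the 2 Ta3 libraries. After blue light it was 19.4, 22.6 and 23.3 CPM in WT, 23.5, 25.5 and 26 in Na1 and 16.6 and 17.3 in Ta3. It rose with blue light in WT (log2 fold change 1.26 ± 0.22, SE), in Na1 (1.20 ± 0.25) and in Ta3 (1.43 ± 0.28). Against WT it did not pass the test in darkness (Na1 0.26 ± 0.26, adjusted p = 0.5, and Ta3 -0.53 ± 0.27, adjusted p = 0.181) or after blue light (Na1 0.20 ± 0.21, adjusted p = 0.508, and Ta3 -0.36 ± 0.24, adjusted p = 0.383). After blue light both Ta3 libraries lay below and all 3 Na1 libraries above the WT libraries, and in darkness the libraries of the lines overlapped those of WT. The library kit named in the labels does not keep the strand, so counts of sense and antisense RNA cannot be told apart here, and the protein was not measured in these data.

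The first comparison asked how WT responded to 1 h of blue light after darkness (n = 3 and 3). Genes of light harvesting and of chlorophyll synthesis rose together. Of the 16 Lhcf antenna genes, which encode fucoxanthin chlorophyll proteins, 14 rose and 1 fell, and all 5 Lhcr antenna genes rose. Examples, each with its log2 fold change and SE, were Lhcf11 (Phatr3_J51230, 4.97 ± 0.15), Lhcf16 (Phatr3_J34536, 5.84 ± 0.29), Lhcr2 (Phatr3_J22956, 6.33 ± 0.50) and Lhcr4 (Phatr3_J17766, 5.91 ± 0.50), while Lhcf15 (Phatr3_J48882, -3.31 ± 0.41) fell. The photoprotective antenna gene Lhcx1 (Phatr3_J27278) went from 39.3 ± 10 to 3201 ± 401 CPM (6.34 ± 0.36, 81.3-fold, adjusted p = 3.08e-09), Lhcx3 (Phatr3_J44733, 3.23 ± 0.25) rose and Lhcx4 (Phatr3_J38720, -2.30 ± 0.21) fell. Of 11 genes of tetrapyrrole synthesis, 9 rose and 1 fell. CHLH (Phatr3_J13265), the magnesium chelatase subunit that commits tetrapyrroles to chlorophyll, went from 5.88 ± 2.47 to 812 ± 93.6 CPM (7.09 ± 0.45), and hemE (Phatr3_J16140, 6.67 ± 0.44), uroporphyrinogen decarboxylase, also rose. In carotenoid synthesis 9 of 10 genes rose, among them ZEP1 (Phatr3_J45845, 6.02 ± 0.31), a zeaxanthin epoxidase, and VDL2 (Phatr3_J45846, 4.25 ± 0.22) and PDS-like1 (Phatr3_J10438, 2.91 ± 0.12). Of the 6 photosystem and electron transport genes, 5 rose, such as PsbO (Phatr3_J20331, 4.15 ± 0.26), OEE3 (Phatr3_J54499, 4.37 ± 0.35) and AtpC (Phatr3_J20657, 4.20 ± 0.15), and petC (Phatr3_J46657, -4.87 ± 0.29) fell. Lhcr2 became 7.03, Lhcr4 6.81 and hemE 7.82 without WT dark replicate 1.

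Against all other genes, the camera set test called the Lhcf (adjusted p = 7.04e-06), Lhcr (0.0319), tetrapyrrole (0.00358), carotenoid (1.59e-04) and photosystem (0.0319) lists and the list of all 27 light-harvesting proteins (3.94e-07), which contains the Lhcf and Lhcr lists, but did not call the list of the 3 Lhcx genes (0.341). None of these calls held with a correlation estimated from the data (adjusted p = 0.373, 0.373, 0.401, 0.0786, 0.392 and 0.261 with an estimated correlation). Adjusted over the list alone, the numbers that rose and fell were 14 and 1 in the Lhcf list, 9 and 1 in the tetrapyrrole list and 9 and 1 in the carotenoid list, as over all genes. Among the blue-light libraries, WT replicate 1, Na1 replicate 3 and Ta3 replicate 1 were grouped because their deviations from the others of their strain were alike. The 2 Ta3 libraries deviated from each other by equal amounts, so replicate 1 was taken only for its likeness to the WT and Na1 libraries. The 3 had median Lhcf deviations of 0.63, 0.44 and 1.05 (log2) and ribosomal protein deviations of -0.56, -0.65 and -0.62. The Lhcr list lost the call (adjusted p = 0.0779 with library sizes alone, 0.0525 without WT dark replicate 2 and 0.0677 without WT dark replicate 3). The photosystem list lost the call (adjusted p = 0.0757 with library sizes alone, 0.0529 without WT dark replicate 1, 0.0555 without WT dark replicate 2 and 0.0648 without WT dark replicate 3).

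Carbon metabolism and lipid synthesis moved with light in WT. Of 21 genes of fatty acid synthesis, elongation and desaturation, 18 rose and 2 fell, with the desaturases FAD2 (Phatr3_J25769, 6.54 ± 0.34), PTD6 (Phatr3_J29488, 6.41 ± 0.28) and PTD15 (Phatr3_J41570, 5.40 ± 0.26) and the ketoacyl synthase FABB (Phatr3_J52648, 3.82 ± 0.22) as examples. This list was called (adjusted p = 3.12e-08), also with an estimated correlation (adjusted p = 0.0455 with an estimated correlation). In glycolysis and gluconeogenesis 13 rose and 5 fell among 19 genes, with Fba3 (Phatr3_J29014, 5.21 ± 0.24), TPI/GapC3 (Phatr3_J25308, 5.39 ± 0.26) and FBP (Phatr3_J23247, 2.84 ± 0.14) higher and PPdK (Phatr3_J21988), pyruvate, phosphate dikinase, lower, from 2465 ± 615 to 117 ± 15.7 CPM (-4.40 ± 0.23). In the Calvin cycle 4 of 5 genes rose, as Rpe (Phatr3_J53935, 5.90 ± 0.19), PGK (Phatr3_J48983, 4.72 ± 0.28) and GapC1 (Phatr3_J22122, 6.0 ± 0.49), and in photorespiration 4 of 6, as GDCP (Phatr3_J22187, 3.52 ± 0.15) and SHMT (Phatr3_J18665, 6.18 ± 0.40). FTHFS (Phatr3_J49229), formate-tetrahydrofolate ligase, went from 0.284 ± 0.183 to 78.9 ± 11.3 CPM (7.98 ± 0.44). All 8 plastid phosphate and nucleotide translocators rose, as NTT5 (Phatr3_J54110, 3.52 ± 0.14) and Tpt3 (Phatr3_J54017, 3.97 ± 0.22), and 7 of 10 genes of pyruvate dehydrogenase and the TCA cycle rose, as PDHB1 (Phatr3_J20183, 3.83 ± 0.21) and SCS-alpha (Phatr3_J42015, 2.36 ± 0.13). Adjusted p for these lists was 0.0319 (glycolysis), 0.0137 (Calvin cycle), 0.0299 (photorespiration), 0.00321 (translocators) and 0.0205 (TCA cycle), and none held, with adjusted p = 0.401, 0.221, 0.158, 0.0786 and 0.138 with an estimated correlation. The glycolysis list lost the call (adjusted p = 0.0736 with library sizes alone, 0.0989 without WT dark replicate 1, 0.0555 without WT dark replicate 2 and 0.0718 without Na1 blue-light replicate 3). The photorespiration list lost the call (adjusted p = 0.0573 without WT dark replicate 3). FTHFS became 8.65 and PGK 5.32 without WT dark replicate 1.

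Cell division, protein folding and repair genes moved both ways, and none of their lists was called. Of 15 DNA replication genes 11 rose, as MCM5 (Phatr3_J11490, 4.24 ± 0.33), MCM4 (Phatr3_J51412, 3.37 ± 0.33) and PCNA (Phatr3_J29196, 1.8 ± 0.18), with a list adjusted p of 0.126. Of 11 diatom-specific cyclins 6 rose and 5 fell (list adjusted p = 0.659), and dsCYC2 (Phatr3_J34956), a cyclin tied to light onset, went from 0.103 ± 0.0982 to 8.38 ± 0.411 CPM. Among chaperones CPN60_2 (Phatr3_J41721, 5.50 ± 0.29) rose, and the small heat shock protein HSP20C (Phatr3_J36981) fell from 3653 ± 367 to 319.9 ± 69.1 CPM (-3.51 ± 0.26). Of 10 DNA repair genes 7 fell, as DDB1 (Phatr3_J29502, -1.16 ± 0.12) and XPF (Phatr3_J30908, -1.46 ± 0.16) (list adjusted p = 0.127). Iron uptake genes ISIP2A (Phatr3_J54465, 5.12 ± 0.25), FRE4 (Phatr3_J54409, 4.62 ± 0.34) and FRE3 (Phatr3_J54940, 2.97 ± 0.23) rose, the first a phytotransferrin and the others named as ferric reductases (list adjusted p = 0.187). All 4 ribosomal protein genes rose, as rpl14 (Phatr3_J50259, 1.38 ± 0.20) and rps19 (Phatr3_J26849, 1.8 ± 0.27) (list adjusted p = 0.381). Smaller or mixed lists, with their median log2 fold change and adjusted p, were kinesins (0.70, 0.341), redox and antioxidant genes (0.51, 0.096), the proteasome (0.55, 0.25), heat shock factors (-1.35, 0.341), nitrogen assimilation and urea cycle (0.22, 0.884) and vesicle coats (0.17, 0.929). Lists with fewer than 3 measured genes were not tested, and their genes were HDS (Phatr3_J44955, -0.37 ± 0.16) of isoprenoid synthesis, GltX (Phatr3_J51214, 1.34 ± 0.13) and GluRS_1 (Phatr3_J51430, 0.19 ± 0.12), 2 aminoacyl-tRNA synthetases, of which HDS and GluRS_1 did not pass, and 2 measured noncoding genes. GluRS_1 passed the test in other settings (0.70 with library sizes alone). HDS passed the test in other settings (-0.42 with RLE factors, -0.42 with DESeq2, -0.39 without the 3 libraries with like deviations and -0.42 with a term for the 3 libraries with like deviations).

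Of the 5 photoreceptors and photolyases in WT, CPF1 (Phatr3_J27429) had a log2 fold change of 0.42 ± 0.15, the phytochrome Dph1 (Phatr3_J54330) of -1.16 ± 0.30, and the photolyases CPD1 (Phatr3_J1947) of -0.27 ± 0.12 and CPD3 (Phatr3_J51952) of -0.12 ± 0.14, and CPD3 did not pass the test. With library sizes alone CPD1 turned to 0.24 and CPD3 to 0.39, and CPD3 then passed the test upward (adjusted p = 0.0351). CPD1 (-0.29) and CPF1 (0.41) lost the call in a fit of the groups compared alone. CPF1 lost it (0.31 without WT dark replicate 3, 0.25 without WT blue-light replicate 1 and 0.24 without the 3 libraries with like deviations). CPD1 lost it (-0.26 without a filter on low counts and -0.27 with the replicate number as a block). Dph1 lost it (-0.66 with library sizes alone). CPD1 lost the call without any 1 of 10 libraries (-0.31 to -0.24). The median of this list was -0.12 (adjusted p = 0.929), and that of 8 other lists was also below 0 but above it with library sizes alone. These were fatty acid activation (-0.45, then 0.06), conserved cyclins (-0.30, then 0.22), cyclin-dependent kinases (-0.11, then 0.41), the anaphase-promoting complex (-0.29, then 0.22), histones (-0.22, then 0.30), chaperones (-0.22, then 0.29), the COP9 signalosome (-0.19, then 0.32) and ubiquitin ligation (-0.46, then 0.06). Their adjusted p was 0.553, 0.881, 0.852, 0.808, 0.884, 0.929, 0.687 and 0.288, in that order. The mean was above 0 while the median was below it for photoreceptors, conserved cyclins, cyclin-dependent kinases, the anaphase-promoting complex, histones and chaperones, and the test pointed up for the last 3 of these.

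By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 8469 genes changed in WT, 4366 higher and 4103 lower, of which 5424 changed at least 2-fold. Further genes chosen by the rule were PHYH (Phatr3_J43737, 6.59 ± 0.48), MASP1 (Phatr3_J46454, 6.5 ± 0.41) and TRD2 (Phatr3_J38413, 6.44 ± 0.67), which rose, and GLO_1 (Phatr3_J16707, -3.59 ± 0.28), DHLTA_4 (Phatr3_J54219, -3.53 ± 0.29), MS (Phatr3_J54478, -3.28 ± 0.24) and TIM_1 (Phatr3_J54738, -3.25 ± 0.20), which fell. Among genes without a symbol, Phatr3_J33726 was at 0 in all 3 dark libraries and at 13.8 ± 2.47 CPM after light, and Phatr3_J44987 (-7.28 ± 0.38) fell. Every library of one group lay above every library of the other for each gene the rule chose by fold change, here and in the other comparisons of 2 groups. The split between higher and lower depends on scaling: with library sizes alone 69.8% of 8336 calls were higher in place of 51.6%, and the median log2 fold change of tested genes was 0.53 in place of 0.03, so changes are relative to that median. MASP1 became 7.10 without WT dark replicate 1. Phatr3_J44987 became -7.89 without WT blue-light replicate 1.

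The same comparison in Na1 (n = 3 after blue light, n = 2 in darkness) gave 15 of 16 Lhcf genes and all 5 Lhcr genes higher, with Lhcf11 (5.39 ± 0.19), Lhcf16 (9.13 ± 0.41) and Lhcr2 (6.60 ± 0.63) as examples and Lhcf15 (-3.52 ± 0.42) lower. GapC4 (Phatr3_J32747), a glyceraldehyde-3-phosphate dehydrogenase, rose from 1.33 ± 1.23 to 959 ± 250.0 CPM (9.53 ± 0.72). ZEP1 (8.48 ± 0.42), FABD (Phatr3_J37652, 8.42 ± 0.48), PHYH (8.64 ± 0.63), FTHFS (8.53 ± 0.49) and PTD12 (Phatr3_J48423, 8.56 ± 0.60) rose, where FABD is the malonyl transferase of fatty acid synthesis. PPdK (-5.40 ± 0.25), PYC1 (Phatr3_J30519, -5.30 ± 0.39), petC (-4.76 ± 0.31), DHLTA_4 (-4.23 ± 0.32), ACD1 (Phatr3_J25932, -3.68 ± 0.24), HSP20C (-3.68 ± 0.27) and ACS3 (Phatr3_J54151, -3.60 ± 0.25) fell, of which PYC1 is a pyruvate carboxylase. Lhcx1 (7.60 ± 0.46) and Lhcx3 (4.06 ± 0.30) rose, Lhcx4 (-2.67 ± 0.22) and Dph1 (-1.66 ± 0.32) fell, CPF1 (0.88 ± 0.17) rose, CPD1 fell (-0.33 ± 0.13), and CPD3 (0.04 ± 0.16, adjusted p = 0.841) did not pass. Lhcf7, chosen by the rule, went from 0.0458 ± 0.0648 to 25.7 ± 1.84 CPM. Among genes without a symbol, Phatr3_J33457 was at 0 in both dark libraries and at 29 ± 5.72 CPM after light, and Phatr3_J45046 (-7.33 ± 0.32) fell. CPD1 lost the call (-0.32 without Na1 dark replicate 1, -0.33 without Na1 dark replicate 2, -0.35 without Na1 blue-light replicate 1, -0.26 without Na1 blue-light replicate 2 and -0.16 with library sizes alone). FTHFS became 7.62, GapC4 8.77, Lhcr2 5.85, PHYH 7.74 and PTD12 7.63 without Na1 dark replicate 1. FTHFS became 10.67, GapC4 11, Lhcr2 7.99, PHYH 10.78 and PTD12 10.99 without Na1 dark replicate 2. Lhcf15 became -4.12 without Na1 blue-light replicate 3.

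Camera called 13 of 33 lists in Na1, all upward, which were the 12 called in WT and redox genes, led by fatty acid synthesis (18 of 21 genes higher, adjusted p = 9.59e-08), light-harvesting proteins (2.06e-07) and Lhcf antenna proteins (4.69e-06). Redox and antioxidant genes were also called (8 of 11 higher, adjusted p = 0.0281), as Trx-y (Phatr3_J33356, 2.73 ± 0.15) and GLRXC2 (Phatr3_J39133, 4.43 ± 0.29). No list held with an estimated correlation, where the smallest adjusted p was 0.0771, for fatty acid synthesis. Adjusted over the list alone, 18 and 3 fatty acid synthesis genes rose and fell. In total 8300 genes changed, 4239 higher and 4061 lower, and 5717 changed at least 2-fold. Under at least 1 alternative or without 1 library the calls of the Calvin cycle (adjusted p up to 0.0738), photosystem (0.0728), photorespiration (0.0824) and redox (0.0523) lists were lost, the photosystem call without WT dark replicate 2 and without Na1 dark replicates 1 or 2.

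In Ta3 (n = 2 and 2) 15 of 16 Lhcf genes and all 5 Lhcr genes rose, with Lhcf11 (4.31 ± 0.18), Lhcf16 (6.93 ± 0.38) and Lhcr2 (6.52 ± 0.63) as examples. FABD (8.76 ± 0.53), FTHFS (8.33 ± 0.54), ZEP1 (8.26 ± 0.44), PHYH (8.03 ± 0.66), GapC1 (7.84 ± 0.66) and PTD6 (7.73 ± 0.37) rose, and the phytotransferrin ISIP2A went from 0.844 ± 0.514 to 173 ± 46.6 CPM (7.64 ± 0.34). petC (-4.81 ± 0.36), ACD1 (-4.46 ± 0.29), PYC1 (-4.21 ± 0.43), DHLTA_4 (-4.07 ± 0.37), PPdK (-3.81 ± 0.28), HSP20C (-3.70 ± 0.32), GLO_1 (-3.47 ± 0.33) and TIM_1 (-3.47 ± 0.25) fell. Lhcx1 (6.53 ± 0.45) and Lhcx3 (4.19 ± 0.32) rose and Lhcx4 (-1.98 ± 0.26) and Dph1 (-1.73 ± 0.36) fell. CPF1 (0.38 ± 0.18, adjusted p = 0.073) did not pass the test. CPD1 (-0.34 ± 0.14) and CPD3 (-0.46 ± 0.17) fell, but turned to 0.19 and 0.07 with library sizes alone. Lhcf7 went from 0.0549 ± 0.0776 to 14.8 ± 7.48 CPM, and Phatr3_J45046 (-7.20 ± 0.38) fell. CPD3 lost the call (-0.49 without Ta3 dark replicate 1, -0.43 without Ta3 dark replicate 2 and -0.37 without Ta3 blue-light replicate 2). CPD1 lost it (-0.33 without a filter on low counts and -0.34 in a fit of the groups compared alone). CPD1 lost the call without any 1 of 7 libraries (-0.34 to -0.20). CPF1 passed the test in other settings (0.91 with library sizes alone, 0.38 in a fit of the groups compared alone and 0.38 with the replicate number as a block). DHLTA_4 became -4.75, Lhcr2 5.87 and PHYH 7.27 without Ta3 blue-light replicate 1. FTHFS became 7.73, GapC1 7.07, Lhcf16 6.27, Lhcr2 5.85, PHYH 7.33 and ZEP1 7.45 without Ta3 dark replicate 1. FTHFS became 9.51, GapC1 9.67, ISIP2A 8.46, Lhcf16 8.33, Lhcr2 8.01, Lhcx1 7.30, PHYH 9.68, PTD6 8.38 and ZEP1 10.67 without Ta3 dark replicate 2.

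Camera called 12 of 33 lists in Ta3, all upward, which were those called in WT without photosystem (adjusted p = 0.0992) and with redox genes (0.0434), led by fatty acid synthesis (18 of 21 genes higher, adjusted p = 8.05e-08) and light-harvesting proteins (1.47e-06). None held with an estimated correlation, where fatty acid synthesis had the smallest adjusted p = 0.0541. Adjusted over the list alone, 19 and 2 of its genes rose and fell. Of the 8264 genes that changed, 4324 were higher and 3940 lower, and 5911 changed at least 2-fold. Without TMM factors, by library sizes alone, 69.7% of 8065 calls were higher in place of 52.3%, and the median of tested genes moved from 0.03 to 0.56 (from 0.01 to 0.17 in Na1). Under at least 1 alternative or without 1 library the calls of the Lhcr (adjusted p up to 0.0902), Calvin cycle (0.0651), photorespiration (0.0805), glycolysis (0.0689) and redox (0.098) lists were lost. The libraries that ended at least 1 of them were WT dark replicates 1 to 3, Ta3 dark replicates 1 and 2 and Na1 blue-light replicate 3, and the photosystem list was called without Ta3 blue-light replicate 2 (adjusted p = 0.0161).

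The light response was shared between the strains. In all 3 strains 3639 genes were higher (647 by the product of the 3 shares) and 3248 lower (531). Across genes the log2 fold changes correlated at 0.936 between WT and Na1, 0.949 between WT and Ta3 and 0.941 between Na1 and Ta3. Genes called in opposite directions numbered 50 for WT and Na1, 11 for WT and Ta3, and 28 for Na1 and Ta3. Genes are not independent replicates, so no p is given for these overlaps.

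**Figure D2:**
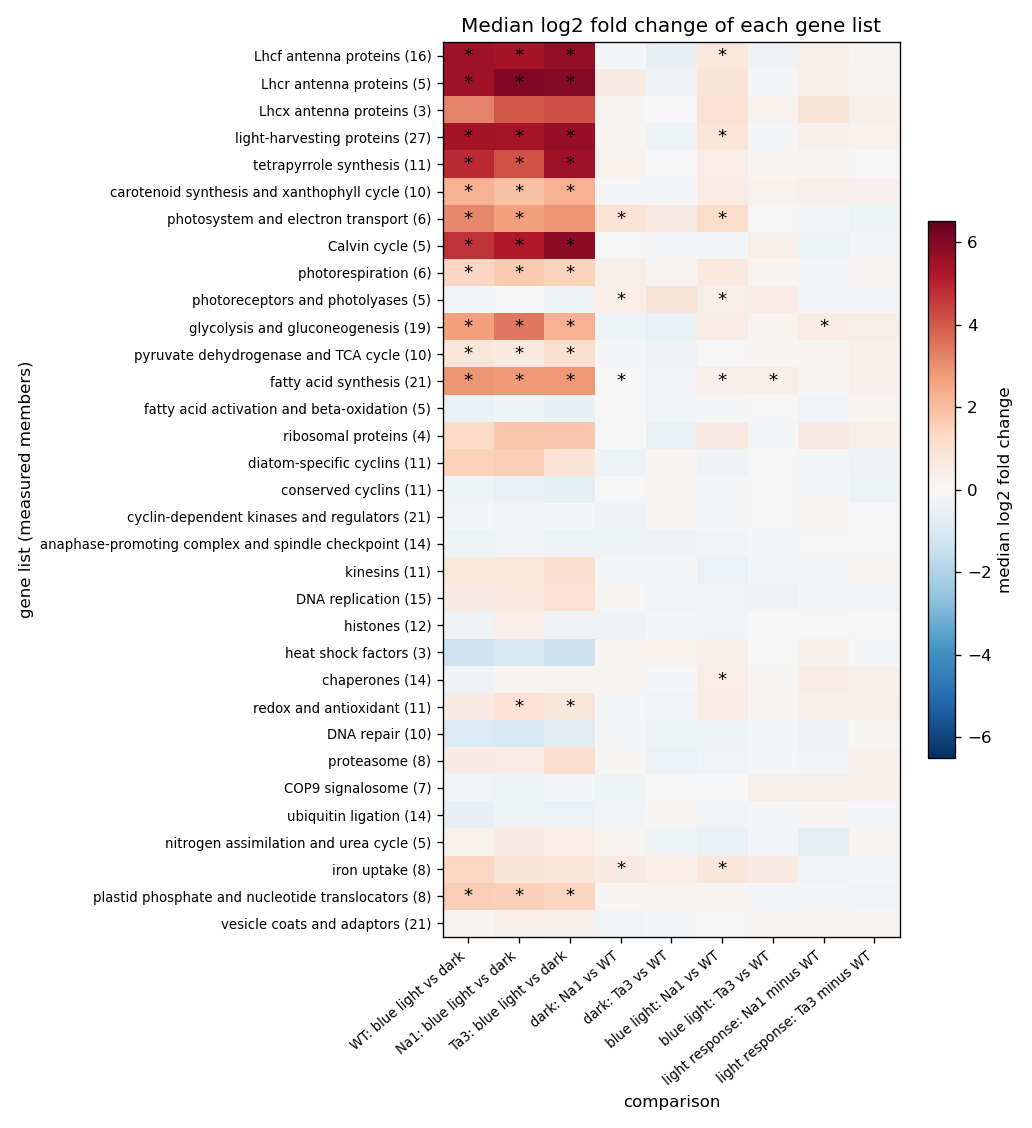
Median log2 fold change of each of the 33 gene lists (rows, measured members in brackets) in 9 comparisons (columns), from blue (lower) to red (higher), with TMM scaling. A star marks camera adjusted p under 0.05 at a preset correlation of 0.01, and 12, 13 and 12 lists carry one in the light responses of WT, Na1 and Ta3. Medians near 0 can change sign with library sizes alone, as for photoreceptors in WT (-0.12 to 0.39).

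In darkness Na1 (n = 2) was set against WT (n = 3), which asked what the antisense line changed without light. The ketoacyl synthase gene FABFa (Phatr3_J37367) rose from 4.13 ± 1.29 CPM in WT to 46.4 ± 2.11 in Na1 (3.50 ± 0.23, 11.3-fold, adjusted p = 2.33e-07), and the ketoacyl reductase gene FABG (Phatr3_J13073) fell from 45.8 ± 10.4 to 5.51 ± 0.11 CPM (-3.05 ± 0.35). Of 21 genes of fatty acid synthesis 8 rose and 3 fell (9 and 3 adjusted over the list alone), also FABB (1.85 ± 0.23) and ACC2 (Phatr3_J55209, 1.56 ± 0.20), the second an acetyl-CoA carboxylase. Iron uptake genes rose in 4 of 8 cases (4 adjusted over the list alone), with FRE4 going from 11.2 ± 3.5 to 123 ± 65.4 CPM (3.46 ± 0.35), and FRE3 (1.82 ± 0.24), FRE5 (Phatr3_J54982, 1.93 ± 0.47) and FRE1 (Phatr3_J54486, 0.62 ± 0.16). Of 6 photosystem genes 3 rose, OEE3 (2.74 ± 0.38), PsbM (Phatr3_J55057, 1.72 ± 0.22) and PsbO (1.61 ± 0.26). The photoreceptors CPF1 (1.41 ± 0.17) and Dph1 (1.37 ± 0.32) and the photolyase CPD1 (0.43 ± 0.13) rose, and CPD3 did not pass (0.09 ± 0.16, adjusted p = 0.72). CPD1 (0.42) and FRE1 (0.44) lost the call without Na1 dark replicate 1. CPD1 (0.43) and FRE5 (1.69) lost the call without Na1 dark replicate 2. CPD1 (0.47) and FRE1 (0.65) lost the call in a fit of the groups compared alone. CPD1 lost it (0.37 without WT dark replicate 1). FRE4 became 2.77 without Na1 dark replicate 1. FRE5 became 2.85 without WT dark replicate 3.

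Other genes higher in Na1 were SHMT (2.36 ± 0.42), Lhcr12 (Phatr3_J54027, 1.89 ± 0.54) and Lhcx4 (0.94 ± 0.21). Lower were METH (Phatr3_J23399, -1.44 ± 0.22), dsCYC5 (Phatr3_J32087, -1.42 ± 0.27), AOX1 (Phatr3_J19979, -1.35 ± 0.20), ARP (Phatr3_J20837, -1.27 ± 0.16), Pt-KIF11 (Phatr3_J13169, -1.25 ± 0.12), Pt-KIF13 (Phatr3_J7359, -1.47 ± 0.34) and HSF2 (Phatr3_J55070, -1.15 ± 0.31), of which METH is a methionine synthase, AOX1 the alternative oxidase and the last a heat shock factor. Lhcx1 (-0.08 ± 0.33, adjusted p = 0.889) and Lhcx3 (0.17 ± 0.27, adjusted p = 0.701) did not pass. Among genes without a symbol, Phatr3_EG01397 was at 0 in the 3 WT libraries and at 11.8 ± 8.28 CPM in Na1, and Phatr3_EG00309 (-4.0 ± 0.37) fell. HSF2 (-0.91) and Lhcr12 (2.01) lost the call without Na1 dark replicate 2. Lhcr12 (1.76) and Pt-KIF13 (-1.15) lost the call without Na1 dark replicate 1. Lhcr12 lost it (1.65 without WT dark replicate 2 and 1.81 without WT dark replicate 3). HSF2 lost it (-1.12 in a fit of the groups compared alone). Phatr3_EG00309 became -4.68 without Na1 dark replicate 2.

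In this comparison 2974 genes differed, 1291 higher and 1683 lower, and 1396 differed at least 2-fold. Camera called 4 of 33 lists upward, iron uptake (adjusted p = 0.0177), photosystem (0.0481), photoreceptors (0.0481) and fatty acid synthesis (0.0481, median 0.03), and none held (adjusted p = 0.515 for each with an estimated correlation). Without WT dark replicate 3 the adjusted p was 0.179 for photosystem and fatty acid synthesis and 0.064 for photoreceptors, and with library sizes alone 0.0511 for all 3. A fit of the groups compared alone ended the calls of photoreceptors (0.0674) and fatty acid synthesis (0.0714), and without Na1 blue-light replicate 3 the adjusted p of all 3 was 0.0551. The photoreceptor call was lost without any 1 of 11 libraries and the fatty acid call without any 1 of 6. The photorespiration list was called without WT dark replicate 1 (adjusted p = 0.0384). The gene count moved to 1644 without Na1 dark replicate 1 and 1756 without Na1 dark replicate 2, and a fit of the groups compared alone gave 1758. Of 2854 calls with library sizes alone 59.2% were higher in place of 43.4%.

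Ta3 in darkness (n = 2) was compared with the same WT libraries (n = 3). The carotenoid isomerase family gene CRTISO3 (Phatr3_J54842) fell from 115 ± 4.59 to 21.9 ± 0.989 CPM (-2.39 ± 0.13, adjusted p = 2.52e-07). FABFa rose to 40.5 ± 6.75 CPM (3.30 ± 0.23), FABB rose (1.63 ± 0.23) and FABG fell (-1.8 ± 0.32), so that 4 of 21 fatty acid synthesis genes rose and 3 fell (5 and 4 adjusted over the list alone). CPF1 (1.16 ± 0.17), Dph1 (1.57 ± 0.32) and CPD3 (0.85 ± 0.16) rose, while CPD1 (0.36 ± 0.13, adjusted p = 0.0589) did not pass. CREG1 (Phatr3_J51183, 3.93 ± 0.36), FRE5 (2.12 ± 0.47), PYC1 (1.8 ± 0.34) and LLA1 (Phatr3_J48875, 1.30 ± 0.25) rose. Lower were ATPase-P4 (Phatr3_J52368, -1.56 ± 0.22), UBC1 (Phatr3_J30389, -1.39 ± 0.21), fru2 (Phatr3_J48054, -1.36 ± 0.19), RAD50 (Phatr3_J51876, -1.27 ± 0.16), RNAP-II_1 (Phatr3_J52094, -1.27 ± 0.25) and EPSPsy (Phatr3_J18246, -1.22 ± 0.26), of which fru2 is a frustulin, RAD50 a DNA repair protein and EPSPsy an enzyme of the shikimate pathway. Lhcx4 fell (-0.64 ± 0.22), and Lhcx1 (0.03 ± 0.33) and Lhcx3 (-0.01 ± 0.27) did not pass (adjusted p = 0.96 and 0.989). Without a symbol, Phatr3_J45614 (5.52 ± 0.48) and Phatr3_EG02027 (4.55 ± 0.47) rose and Phatr3_J48309 (-6.5 ± 0.27) fell. EPSPsy lost the call (-0.97 without Ta3 dark replicate 1). Lhcx4 lost it (-0.64 with RLE factors, -0.63 with a stricter filter, -0.62 in a fit of the groups compared alone and -0.62 without the 3 libraries with like deviations). Lhcx4 lost the call without any 1 of 13 libraries (-0.73 to -0.39). CPD1 passed the test in other settings (0.36 with DESeq2, 0.38 without the 3 libraries with like deviations and 0.36 with a term for the 3 libraries with like deviations). FRE5 became 3.04 and Phatr3_J45614 6.13 without WT dark replicate 3.

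A total of 2645 genes differed, 1105 higher and 1540 lower, and 1145 differed at least 2-fold. Camera called 0 of 33 lists, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0745, for photoreceptors and photolyases. That list was called with the replicate number as a block (adjusted p = 0.0169), with a term for the 3 libraries with like deviations (0.0441), and without WT dark replicate 3 (0.0408), Ta3 dark replicate 1 (0.0293) or WT blue-light replicate 1 (0.0449). The gene count fell to 1246 without Ta3 dark replicate 2, and to 1259 without Ta3 dark replicate 1. A fit of the groups compared alone gave 1504, and with library sizes alone 29.6% of 2640 calls were higher in place of 41.8%.

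In darkness 424 genes were higher and 648 lower than WT in both lines, and 84 differed in opposite directions. Genes with a symbol that met the rule were ranked by the smaller of the 2 changes. Their largest rises were FABFa (Na1 3.50, Ta3 3.30), FRE5 (1.93, 2.12), FABB (1.85, 1.63), SHMT (2.36, 1.52) and Dph1 (1.37, 1.57). Their largest falls were FABG (-3.05, -1.8), CRTISO3 (-1.04, -2.39), APC6 (Phatr3_J1550) of the anaphase-promoting complex (-0.92, -0.94), UBC1 (-0.87, -1.39) and AOX1 (-1.35, -0.84). Phatr3_J48071, without a symbol, fell from 16.9 ± 2.66 CPM in WT to 1.25 ± 0.738 in Na1 and 0.455 ± 0.133 in Ta3. Independent lists would share 128 higher and 233 lower genes, with 346 in opposite directions, but both lines were set against the same 3 WT libraries. In 20 simulations of lines that do not differ from WT, 0 genes were called in both, and the log2 fold changes correlated at 0.391 across genes, against 0.519 observed. No line effect was simulated, so the 0 says nothing about lines whose effects are unrelated. Each gene had the same simulated spread in all groups. The WT dark pairs differed more (chi-square per degree of freedom 42.1 to 44) than the Na1 (15.2) and Ta3 (10.6) dark pairs, so the simulated covariance may be too low. The observed covariance exceeded the simulated 0.0461 by 0.367, but part of the excess can still come from the shared libraries, since 3 cannot be divided into groups of 2. FRE5 lost the call (1.69 without Na1 dark replicate 2). UBC1 lost it (-0.71 without Na1 dark replicate 1). FRE5 became 2.85 without WT dark replicate 3. In Ta3 AOX1 (-0.86) and SHMT (1.15) lost the call without Ta3 dark replicate 2. AOX1 lost it (-0.82 without Ta3 dark replicate 1). SHMT lost it (1.39 without WT dark replicate 2). FRE5 became 3.04 without WT dark replicate 3. The shared count of 1072 fell to 585 without Ta3 dark replicate 1, to 585 without Ta3 dark replicate 2, to 693 and 692 without Na1 dark replicates 1 and 2, and to 515 in fits of the groups compared alone.

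After blue light Na1 (n = 3) was set against WT (n = 3). Lhcx1 rose from 3201 ± 401 CPM in WT to 7235 ± 521 in Na1 (1.18 ± 0.29, adjusted p = 0.00619), and Lhcx3 (1.00 ± 0.22) and Lhcx4 (0.57 ± 0.21) rose too. Of all 27 light-harvesting genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), as Lhcf16 (1.63 ± 0.21), Lhcr11 (Phatr3_J23257, 2.06 ± 0.40) and Lhcr8 (Phatr3_J32294, 0.82 ± 0.17), and of 6 photosystem genes 4 rose, AtpC (1.85 ± 0.13), PsbM (1.32 ± 0.20), PsbO (1.22 ± 0.23) and OEE3 (1.18 ± 0.28). The iron gene ISIP2A went from 64.8 ± 2.14 to 495 ± 21.2 CPM (2.94 ± 0.19), and FRE1 (0.94 ± 0.15) and FRE4 (0.99 ± 0.29) rose. FABFa went from 31.5 ± 1.02 to 252 ± 33.9 CPM (3.0 ± 0.19), FABD (2.69 ± 0.27), FABI (Phatr3_J10068, 2.46 ± 0.31), ACC2 (1.78 ± 0.19) and FABB (1.65 ± 0.20) rose and FABG fell (-1.98 ± 0.26), with 9 of 21 fatty acid synthesis genes higher and 2 lower (10 and 2 adjusted over the list alone). Among chaperones 5 of 14 rose, as HSP70F (Phatr3_J41417, 1.06 ± 0.15), HSP70A (Phatr3_J54019, 1.02 ± 0.21) and CPN60_1 (Phatr3_J24820, 0.78 ± 0.20). CPF1 (1.86 ± 0.15), Dph1 (0.86 ± 0.29) and CPD1 (0.37 ± 0.12) rose, and CPD3 (0.25 ± 0.14, adjusted p = 0.204) did not pass. The antenna deviations of WT replicate 1 (0.63) and Na1 replicate 3 (0.44), given above, lie within these groups. CPD1 (0.34) and Dph1 (0.78) lost the call without WT blue-light replicate 2. CPD1 (0.37) and Dph1 (0.88) lost the call without WT blue-light replicate 3. CPD1 (0.34), Dph1 (0.51) and FRE4 (0.66) lost the call without Na1 blue-light replicate 3. CPD1 (0.16), Dph1 (0.65) and Lhcx4 (0.36) lost the call with library sizes alone. Dph1 (0.59), FRE4 (0.65) and Lhcx4 (0.63) lost the call without the 3 libraries with like deviations. CPD1 lost it (0.35 without Na1 blue-light replicate 1). Dph1 lost it (0.94 without WT blue-light replicate 1). Lhcx4 lost it (0.57 without a filter on low counts). Lhcx4 lost the call without any 1 of 12 libraries (0.44 to 0.67).

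Other genes higher in Na1 were SLC4A_1 (Phatr3_J45656, 3.37 ± 0.31), dsCYC4 (Phatr3_J43034, 2.51 ± 0.30), NDK1 (Phatr3_J41676, 2.51 ± 0.23) and DHLTA_3 (Phatr3_J23850, 2.30 ± 0.25), the first of a bicarbonate transporter family. Lower were SMP1 (Phatr3_J44694, -2.80 ± 0.63), PYC1 (-2.31 ± 0.35), PPdK (-1.64 ± 0.21), dsCYC5 (-1.57 ± 0.25), SMC2 (Phatr3_J30352, -1.48 ± 0.30), DHLTA_4 (-1.43 ± 0.29) and GWT1 (Phatr3_J54588, -1.41 ± 0.11). Phatr3_J45413, without a symbol, was at 0.0218 ± 0.0377 CPM in WT and 22.7 ± 2.94 in Na1, and Phatr3_J43971 (5.34 ± 0.36) rose. In all 3707 genes differed, 1713 higher and 1994 lower, and 1524 differed at least 2-fold. Camera called 7 of 33 lists upward, fatty acid synthesis (adjusted p = 8.27e-04), light-harvesting proteins (0.00339), photosystem (0.00339), chaperones (0.0325), iron uptake (0.0325), photoreceptors (0.0366) and Lhcf antenna proteins (0.0383). None held (adjusted p = 0.457, 0.559, 0.465, 0.559, 0.465, 0.465 and 0.629 with an estimated correlation). Without Na1 blue-light replicate 3 only 3 calls were left, the last 4 having adjusted p = 0.114 for chaperones, iron uptake and photoreceptors and 0.151 for Lhcf. Without WT blue-light replicate 2 or 3 the iron uptake and photoreceptor (0.0663, 0.0601) and Lhcf (0.0969, 0.0992) calls were lost, as was that of Lhcf without WT dark replicate 3 (0.0515) and that of photoreceptors with library sizes alone (0.0521) or without the 3 libraries with like deviations (0.0575). The Lhcr list was called without those 3 (0.0196) and with a term for them (0.04). With library sizes alone 24.7% of 4224 calls were higher in place of 46.2%, and the median of tested genes moved from 0.01 to -0.21.

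In Ta3 after blue light (n = 2, against 3 WT libraries) FABFa rose to 135 ± 29.6 CPM (2.10 ± 0.19), FABD (1.81 ± 0.29) and FABI (1.34 ± 0.33) rose and FABG fell (-1.49 ± 0.30), with 7 of 21 fatty acid synthesis genes higher and 2 lower (9 and 2 adjusted over the list alone). CRTISO3 fell from 152 ± 3.79 to 49.7 ± 4.45 CPM (-1.62 ± 0.12, adjusted p = 3.29e-06). ISIP2A (1.42 ± 0.20), GrpE (Phatr3_J12896, 1.25 ± 0.16), DHLTA_3 (1.16 ± 0.26) and RNAP-II_3 (Phatr3_J35680, 1.08 ± 0.25) rose, where GrpE is a partner of HSP70. Lower were HSP70B (Phatr3_J46333, -2.49 ± 0.34), TRD2 (-2.14 ± 0.51), CYCD1 (Phatr3_J29283, -1.63 ± 0.29), MCM4 (-1.57 ± 0.32), fru2 (-1.45 ± 0.19) and RabGDI (Phatr3_J14827, -1.43 ± 0.17), with MCM4 a subunit of the replicative helicase and CYCD1 a D-type cyclin. CPF1 (1.11 ± 0.16) and CPD3 (0.50 ± 0.16) rose, and Dph1 (0.99 ± 0.32, adjusted p = 0.0525) and CPD1 (0.29 ± 0.13, adjusted p = 0.165) did not pass. Of the antenna genes Lhcx3 rose (0.96 ± 0.25), and Lhcx1 (0.21 ± 0.32) and Lhcx4 (-0.32 ± 0.24) did not pass (adjusted p = 0.738 and 0.459). Without a symbol, Phatr3_EG02149 was at 0 in every WT and Na1 library and at 10.2 ± 1.16 CPM in Ta3, Phatr3_EG02027 (4.33 ± 0.47) rose and Phatr3_J49557 (-4.70 ± 0.62) fell. DHLTA_3 (0.88), FABI (0.84), Lhcx3 (0.42) and RNAP-II_3 (0.89) lost the call without Ta3 blue-light replicate 2. CPD3 (0.49), Lhcx3 (0.95) and TRD2 (-2.15) lost the call in a fit of the groups compared alone. TRD2 lost it (-1.64 without Ta3 blue-light replicate 1). CPD3 lost it (0.42 with library sizes alone, 0.50 without a filter on low counts, 0.50 with the replicate number as a block and 0.52 without the 3 libraries with like deviations). CPD3 lost the call without any 1 of 9 libraries (0.40 to 0.59). Dph1 passed the test in other settings (0.99 with RLE factors, 0.99 with DESeq2, 0.98 in a fit of the groups compared alone, 1.20 with the replicate number as a block and 0.94 with a term for the 3 libraries with like deviations). FABG became -2.18, Phatr3_EG02027 3.60 and TRD2 -2.91 without Ta3 blue-light replicate 2.

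Here 1690 genes differed, 798 higher and 892 lower, and 689 differed at least 2-fold. Camera called 1 of 33 lists, fatty acid synthesis (adjusted p = 0.0392), which did not hold (adjusted p = 0.777 with an estimated correlation). Its call was lost with the replicate number as a block (0.0515) and without WT blue-light replicate 1 (0.0743), Na1 blue-light replicate 2 (0.0531) or Ta3 blue-light replicate 2 (0.132). The antenna lists were not called (Lhcf adjusted p = 0.781), and the Lhcf genes lay a median of 1.05 higher in Ta3 replicate 1 than in replicate 2. Without Ta3 blue-light replicate 1 the COP9 signalosome list was called (adjusted p = 0.0332), and without the 3 libraries with like deviations it (0.0292) and chaperones (0.0292) were called. The gene count moved to 1096 without WT blue-light replicate 2 and 820 without Ta3 blue-light replicate 2. Of 1560 calls with library sizes alone 35.2% were higher in place of 47.2%.

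After blue light 367 genes were higher and 557 lower in both lines, and 50 differed in opposite directions. Genes with a symbol were ranked as in darkness. Their largest rises were FABFa (Na1 3.0, Ta3 2.10), FABD (2.69, 1.81), ISIP2A (2.94, 1.42), FABI (2.46, 1.34), DHLTA_3 (2.30, 1.16) and CPF1 (1.86, 1.11). Their largest falls were FABG (-1.98, -1.49), RAD50 (-1.11, -1.17), MCM7 (Phatr3_J13243) (-0.99, -1.14), ACD1 (-0.96, -1.08), GapC2a (Phatr3_J51128) (-0.83, -1.23) and CRTISO3 (-0.73, -1.62). Phatr3_J49557 fell from 122 ± 45.5 CPM in WT to 2.62 ± 0.67 in Na1 and 4.67 ± 1.62 in Ta3. Independent lists would share 123 higher and 160 lower genes, with 281 in opposite directions. In 20 simulations of unchanged lines against the shared WT libraries 0 genes were called in both, with a correlation of 0.437 across genes against 0.546 observed. As in darkness, no line effect was simulated, so the 0 says nothing about lines whose effects are unrelated. The covariance exceeded the simulated 0.0314 by 0.332, part of which can come from the shared libraries. MCM7 lost the call (-0.99 without the 3 libraries with like deviations and -1.03 to -0.93 without any 1 of 5 libraries). In Ta3 DHLTA_3 (0.88) and FABI (0.84) lost the call without Ta3 blue-light replicate 2. ACD1 lost it (-0.71 without Ta3 blue-light replicate 1). MCM7 lost it (-1.05 with the replicate number as a block and -1.54 without the 3 libraries with like deviations). MCM7 lost the call without any 1 of 11 libraries (-1.49 to -0.87). FABG became -2.18 without Ta3 blue-light replicate 2. The shared count of 924 moved to 578 without WT blue-light replicate 2, 609 without WT blue-light replicate 3 and 487 without Ta3 blue-light replicate 2, and with library sizes alone 23.3% of 997 were higher in place of 39.7%.

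**Figure D3:**
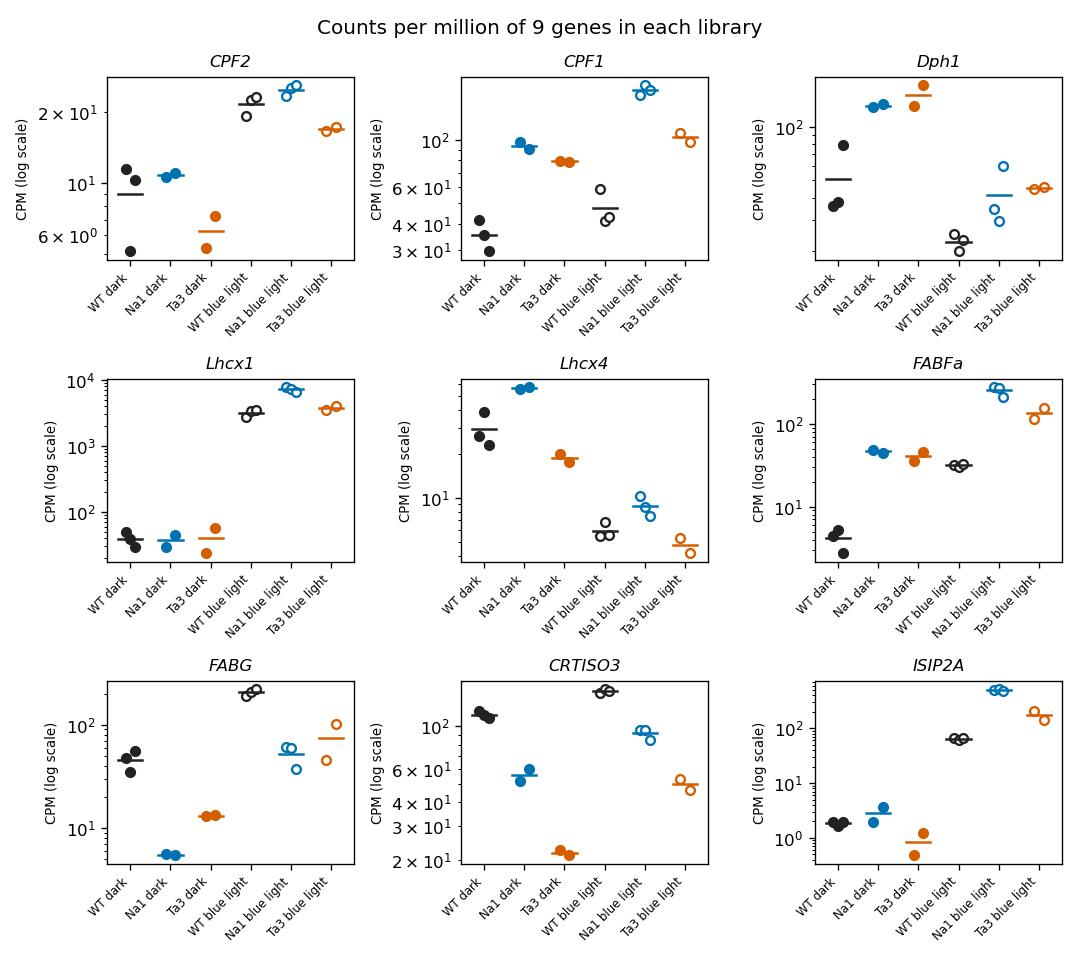
Normalised level in CPM (log scale) of 9 genes in each of the 15 libraries, with 1 point per library, a line at the group mean, and colour by strain. The level of CPF2 overlaps between the lines and WT in darkness but not after blue light, FABFa lies higher and FABG lower in both antisense lines in darkness and after blue light, and ISIP2A lies higher in both lines after blue light.

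Whether the light response itself differed from WT was tested as an interaction. In Na1 the log2 difference was positive for GapC4 (3.45 ± 0.78), FBP (2.29 ± 0.21), GapC1 (2.30 ± 0.63), TPI/GapC3 (1.79 ± 0.37) and PK1 (Phatr3_J22404, 1.17 ± 0.21). FBP is fructose-1,6-bisphosphatase and PK1 a pyruvate kinase. The difference was negative for PYC1 (-2.42 ± 0.48), which fell more with light in Na1 than in WT. Lhcf16 (3.29 ± 0.53), ZEP1 (2.47 ± 0.55), FABD (2.85 ± 0.65), FABI (2.44 ± 0.66) and ISIP2A (2.36 ± 0.38) also rose more in Na1. Lower responses were found for the ferric reductases FRE4 (-2.47 ± 0.44) and FRE3 (-1.96 ± 0.32), FSA (Phatr3_J20779, -2.37 ± 0.51) and Pt-KIF6 (Phatr3_J15853, -2.07 ± 0.17), MCM4 (-1.92 ± 0.46), SMC (Phatr3_J43956, -1.64 ± 0.32) and KAS1 (Phatr3_J26714, -1.58 ± 0.36). The kinesin Pt-KIF6 rose with light in WT (0.71 ± 0.11) and fell in Na1 (-1.36 ± 0.12). Without a symbol, Phatr3_EG00885 (4.62 ± 0.82) was higher and Phatr3_J26948 (-4.50 ± 0.54) and Phatr3_EG00203 (-4.26 ± 0.48) lower. None of the 5 photoreceptors and photolyases or 3 Lhcx genes passed, and Lhcx1 was nearest with 1.26 ± 0.44 (adjusted p = 0.114). FABD (2.48) and ZEP1 (2.19) lost the call without WT dark replicate 1. FABD (2.41), FRE4 (-1.79), FSA (-1.20), GapC4 (2.69), KAS1 (-1.56), MCM4 (-1.27), TPI/GapC3 (1.74) and ZEP1 (2.59) lost the call without Na1 dark replicate 1. FABD (2.73), GapC4 (3.33), KAS1 (-1.50) and ZEP1 (2.44) lost the call without Na1 blue-light replicate 1. KAS1 (-1.61), PYC1 (-2.18), SMC (-1.33), TPI/GapC3 (1.83) and ZEP1 (2.37) lost the call without Na1 dark replicate 2. KAS1 (-1.47) and MCM4 (-1.93) lost the call without Na1 blue-light replicate 2. FABD lost it (2.63 without WT dark replicate 2). MCM4 lost it (-1.89 without WT blue-light replicate 2, -1.81 without WT blue-light replicate 3 and -1.92 in a fit of the groups compared alone). GapC1 lost it (1.97 with library sizes alone, 2.38 with the replicate number as a block and 2.28 without the 3 libraries with like deviations). FABI lost the call without any 1 of 9 libraries (2.05 to 2.95). GapC1 lost the call without any 1 of 12 libraries (1.96 to 2.74). Lhcx1 passed the test in other settings (1.28 with DESeq2). FSA became -2.98 and GapC4 4.92 without Na1 dark replicate 2. Phatr3_EG00203 became -5.04 without WT dark replicate 2. Phatr3_EG00885 became 5.30 without Na1 dark replicate 1.

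In total 619 genes passed, 268 with a higher and 351 with a lower response, and 433 differed at least 2-fold. Camera called 1 of 33 lists, glycolysis and gluconeogenesis (5 of 19 genes higher, 1 lower, 7 and 2 adjusted over the list alone, adjusted p = 0.0101), which did not hold (adjusted p = 0.812 with an estimated correlation). Its call was lost with the replicate number as a block (0.0533) and without WT dark replicate 3 (0.126), Na1 dark replicate 1 (0.0626), Na1 blue-light replicate 3 (0.0972) or the 3 libraries with like deviations (0.168). With library sizes alone the light-harvesting (adjusted p = 0.00462) and Lhcf (0.0153) lists were called upward against all other genes, though the medians of their own log2 differences went from 0.27 and 0.35 to -0.07 and 0.00. Without WT blue-light replicate 1 light-harvesting proteins were called upward and kinesins downward (0.0393 each). The gene count moved to 167 without Na1 dark replicate 1, 267 without Na1 dark replicate 2, 286 without WT blue-light replicate 2, 327 without WT blue-light replicate 3, 249 without Na1 blue-light replicate 1 and 323 without Na1 blue-light replicate 2. With library sizes alone 1307 genes passed, 7.42% of them higher in place of 43.3%, and the median of tested genes moved from 0.03 to -0.32.

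In Ta3 the log2 difference in light response from WT was positive for ISIP2A (2.52 ± 0.46), FABFb (Phatr3_J18940, 1.27 ± 0.22), a ketoacyl synthase, and APC6 (0.95 ± 0.19). The difference was negative for Pt-KIF6 (-1.47 ± 0.18), which rose with light in WT and fell in Ta3 (-0.76 ± 0.14). The call of its fall in Ta3 was lost with library sizes alone (-0.23). ISIP2A, FABFb, APC6 and Pt-KIF6 were the only genes with a symbol that the rule chose. Without a symbol, Phatr3_J48309 (5.05 ± 0.34) was higher and Phatr3_J14688 (-4.13 ± 0.30) and Phatr3_J34672 (-2.93 ± 0.46) lower. None of the photoreceptors, photolyases or Lhcx genes passed. In total 97 genes passed, 64 higher and 33 lower, and 83 at least 2-fold. Camera called 0 of 33 lists, 4 had an unadjusted p under 0.05, and the smallest adjusted p was 0.104, for conserved cyclins, which were called without WT dark replicate 1 (0.0155), WT blue-light replicate 1 (0.0304) or Ta3 blue-light replicate 2 (0.0455). The carotenoid list was called without Ta3 blue-light replicate 2 (0.0455), and chaperones without the 3 libraries with like deviations (0.00821). ISIP2A (2.03) and Phatr3_J34672 (-2.82) lost the call without Ta3 dark replicate 1. APC6 (0.91), FABFb (1.24) and ISIP2A (2.48) lost the call in a fit of the groups compared alone. ISIP2A lost it (2.49 without WT blue-light replicate 2 and 2.53 without WT blue-light replicate 3). Phatr3_J34672 lost it (-2.87 without Ta3 blue-light replicate 2). APC6 lost it (0.95 with the replicate number as a block and 0.91 without the 3 libraries with like deviations). APC6 lost the call without any 1 of 11 libraries (0.82 to 1.09). FABFb lost the call without any 1 of 5 libraries (1.19 to 1.29). ISIP2A became 3.34 without Ta3 dark replicate 2. The count moved to 293 without WT dark replicate 2, 179 without WT dark replicate 3, 64 without Na1 dark replicate 2, 20 without Ta3 dark replicate 1, 25 without Ta3 dark replicate 2, 34 without WT blue-light replicate 2, 33 without WT blue-light replicate 3, 48 without Na1 blue-light replicate 1, 59 without Na1 blue-light replicate 2, 64 without Ta3 blue-light replicate 1 and 19 without Ta3 blue-light replicate 2, and was 16 in a fit of the groups compared alone.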

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

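The tests of mixed-in dark RNA, of joint handling, of scaling, of the shared WT libraries and of line history were chosen after the results were seen. Those of depth and of the split of the blue-light libraries were chosen after the 3 libraries with like deviations were seen but before their own values, and that of few reads in darkness before its values were seen.

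The light response differed from WT by the interaction test for 619 genes in Na1. The named genes with a positive log2 difference in Na1 were GapC4 (3.45), Lhcf16 (3.29), FABD (2.85), ZEP1 (2.47), FABI (2.44), ISIP2A (2.36), GapC1 (2.30), FBP (2.29), TPI/GapC3 (1.79), PK1 (1.17) and Phatr3_EG00885 (4.62). Those with a negative difference were FRE4 (-2.47), PYC1 (-2.42), FSA (-2.37), Pt-KIF6 (-2.07), FRE3 (-1.96), MCM4 (-1.92), SMC (-1.64), KAS1 (-1.58), Phatr3_J26948 (-4.50) and Phatr3_EG00203 (-4.26). Of these, PYC1 fell more with light in Na1 than in WT, and Pt-KIF6 rose in WT and fell in Na1. The glycolysis and gluconeogenesis list had adjusted p = 0.0101 at the preset correlation and adjusted p = 0.812 with an estimated correlation, 0.0533 with the replicate number as a block and 0.168 without the 3 libraries with like deviations. It was also lost without WT dark replicate 3 (0.126), Na1 dark replicate 1 (0.0626) or Na1 blue-light replicate 3 (0.0972). In Ta3 97 genes differed, among them ISIP2A (2.52), FABFb (1.27), APC6 (0.95), Pt-KIF6 (-1.47), Phatr3_J48309 (5.05), Phatr3_J14688 (-4.13) and Phatr3_J34672 (-2.93). Between the 2 lines 84 genes in darkness and 50 after blue light were called in opposite directions against WT, and the lines were not tested against each other.

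Of the 619 genes in Na1, 398 differed from WT after blue light, 348 in darkness and 133 in both. Dark levels under 1 CPM do not account for most of them, since 585 had a mean of at least 1 CPM in darkness in both strains. Genes close above that level pass this test, as ISIP2A with 1.62 to 1.96 CPM in the WT dark libraries. The difference of GapC4 was 2.69 without Na1 dark replicate 1 and 4.92 without Na1 dark replicate 2. For genes so close to 1 CPM, few reads stay open as an explanation. Without the 3 blue-light libraries with like deviations, 496 kept their call and direction. That left the close pairs of WT and Na1, whose small spread can favour calls, so this split stays open. With RLE factors 596 kept both, but with library sizes alone 448, so scaling may account for some and stays open. A changed light response of the line is the biological explanation the design offers, not tested apart from the line's history.

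One blue-light library of each strain (WT replicate 1, Na1 replicate 3 and Ta3 replicate 1) deviated from the others of its strain in a similar way. They were picked for this: of 18 choices of 1 library per strain theirs had the highest mean correlation, and the next had 0.378. The deviations of the 3 picked libraries correlated across genes at 0.383 (WT with Na1), 0.436 (WT with Ta3) and 0.434 (Na1 with Ta3). Ta3 has 2 blue-light libraries, whose deviations are mirror images, so the sign of both correlations with Ta3 follows from taking replicate 1. Dark RNA mixed into them would lower light-induced antenna genes, but the median Lhcf deviations of WT replicate 1 and Na1 replicate 3 were 0.63 and 0.44, so it is argued against for these genes in these 2 libraries. In Ta3 the sign of the deviation depends on the replicate taken, so it stays open. For genes with a mean light response beyond 2 (log2) it stays open, since those that fell deviated upward (0.34, 0.32 and 0.18) and those that rose downward (-0.18, -0.12 and -0.03), the direction dark RNA would give. Unequal depth is argued against by a mean correlation of 0.411 after every library was thinned to the smallest total. Joint handling of these cultures or libraries could give the mean correlation of 0.417, but no label marks them, so this cannot be told apart from other causes. No biological explanation was tested, since the design names no group that holds these libraries.

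Both lines differed from WT in the same direction at 1072 genes in darkness and 924 after blue light. Chance values of the shared WT libraries would not recur with other WT libraries if those came from separate cultures, which no label states. In both conditions 421 genes recurred, 140 higher and 281 lower, where independent lists would give 14 and 32.5. The history of the transformed lines or of the WT culture cannot be told apart from the antisense construct, since no transformed line without it was sequenced. Only 10 genes recurred in both conditions with opposite directions in the 2 lines, which may reflect either the construct or a difference between the WT culture and both lines.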

How the results depend on the processing

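Leaving out the 3 blue-light libraries with like deviations and giving them a term in the model were chosen after the data were seen, and all other alternatives before.

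Counts of called genes stayed within 1.5 times under RLE factors, both filters, the replicate block and the 3 libraries left out, for all 11 comparisons. They moved in these cases, and the cause was not tested except where named. With library sizes alone, the Na1 interaction had 1307 genes in place of 619. DESeq2 gave 1128 for it and 353 for the Ta3 interaction (97). The term for the 3 libraries gave 1214 and 479. A fit of the groups compared alone has fewer libraries to estimate the spread, and gave 1758 genes for Na1 in darkness (2974), 1504 for Ta3 in darkness (2645), 515 for both lines in darkness (1072) and 16 for the Ta3 interaction. A 2-fold threshold selects by size, and left 5424 genes for WT light (8469), 1396 and 1145 for Na1 and Ta3 in darkness, 1524 and 689 for them after blue light (3707 and 1690), and 423 and 349 for both lines in darkness and after blue light.

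Leaving out 1 library at a time, the count ran from 7931 to 8552 for WT light, 7473 to 8451 for Na1 light and 7365 to 8403 for Ta3 light. In darkness it ran from 1644 (without Na1 dark replicate 1) to 3154 for Na1, from 1246 (without Ta3 dark replicate 2) to 2869 for Ta3, and from 585 (without Ta3 dark replicate 1) to 1175 for both lines. After blue light it ran from 2849 to 3988 for Na1, from 820 (without Ta3 blue-light replicate 2) to 1928 for Ta3, and from 487 (without the same library) to 1062 for both lines. The Na1 interaction ran from 167 (without Na1 dark replicate 1) to 918, and the Ta3 interaction from 19 (without Ta3 blue-light replicate 2) to 293 (without WT dark replicate 2). A lone library left in a group was assumed to vary like the other groups.

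Called gene lists depended on the correlation: with one estimated from the data 1 list was called in WT light in place of 12, and 0 in Na1 light (13), Ta3 light (12), Na1 in darkness (4), Na1 and Ta3 after blue light (7 and 1) and the Na1 interaction (1), where the raw p was under 0.05 for 13, 14, 13, 6, 12, 5 and 7 lists at the preset correlation. A fit of the groups compared alone gave 7 lists in Ta3 light and 2 for Na1 in darkness. Library sizes alone gave 1 for Na1 in darkness and 3 for the Na1 interaction. The replicate block gave 1 for Ta3 in darkness (0), 0 for Ta3 after blue light and 0 for the Na1 interaction. Without the 3 libraries with like deviations there were 2 for Na1 in darkness, 3 for Ta3 after blue light, 0 for the Na1 interaction and 1 for the Ta3 interaction (0), and their term gave 1 for Ta3 in darkness. Without 1 library at a time the number of lists ran from 9 to 12 (WT light), 12 to 13 (Na1 light), 8 to 13 (Ta3 light), 1 to 5 and 0 to 1 (Na1 and Ta3 in darkness), 3 to 7 and 0 to 2 (Na1 and Ta3 after blue light), and 0 to 3 and 0 to 2 (Na1 and Ta3 interactions). The cause was not tested.

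Among named genes, 4 values turned direction, all with library sizes alone: CPD1 and CPD3 in WT light (0.24 and 0.39) and in Ta3 light (0.19 and 0.07). This setting moved the median of all tested genes from 0.03 to 0.53 in WT light and to 0.56 in Ta3 light, which is larger than these changes. Calls were otherwise lost for 14 named values in a fit of the groups compared alone, 8 with library sizes alone, 10 without the 3 libraries, 4 without a filter, 5 with the block, 1 with a stricter filter and 1 with RLE factors. No label pairs the replicate numbers. Deviations of dark and blue-light libraries with the same number correlated at 0.07, 0.03 and 0.19 in WT, -0.19 and 0.20 in Na1 and -0.09 and -0.09 in Ta3. Those of WT and line libraries with the same number correlated at 0.29 and 0.11 (Na1) and -0.04 and -0.21 (Ta3) in darkness, and at -0.38, 0.33 and -0.18 (Na1) and 0.44 and 0.42 (Ta3) after blue light, so a pairing within a condition is not excluded. In simulated data 77 of 100 genes changed 2-fold were found with 3 and 3 libraries and 61 of 100 with 3 and 2, and no simulation varied the depth.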

Other observations

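The counts of genes that recur across conditions were chosen after the data were seen, and the splits of the libraries before.

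In Na1, 692 genes were higher than WT both in darkness and after blue light (199 from independent lists), 995 were lower in both (302) and 57 changed direction. In Ta3 the numbers were 449 (79.3), 593 (124) and 11. The dark and blue-light log2 fold changes correlated across genes at 0.702 in Na1 and 0.648 in Ta3. In both lines and both conditions 140 genes were higher and 281 lower. With a symbol these were 6 higher genes, PDS-like1, CPF1, FABFa, FABB, FABZ_2 and ACC2, and 9 lower ones, UNC18, DRR2, FABG, CAT2, dsCYC6, Rab18, RAD50, RPN6 and CRTISO3. Of the 6, 4 belong to fatty acid synthesis by name, as does FABG among the 9. These overlaps were not recomputed under the alternatives.

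Of the 619 genes whose light response differed in Na1, 38 also differed in Ta3 in the same direction. Both interactions subtract the same WT libraries, and the number that this sharing alone gives was not simulated.

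Splits of the 6 libraries were too few (10) for a share under 0.05, with 1 split, the real one, giving the real count in each case. In WT light, fitted on the 6 libraries alone, the real split gave 8041 calls and the highest of the others 0. For Na1 after blue light it gave 3890 and the highest of the others 0, with up to 92 genes at an unadjusted p under 0.05 among the other splits in WT light and up to 497 in Na1. The edgeR quasi-likelihood test was the tool used for these splits. Every other split put libraries of both real groups on each side, which widens the spread within each side. Their 0 calls were thus to be foreseen and are no check on chance.

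In the 3 blue-light libraries with like deviations (WT replicate 1, Na1 replicate 3 and Ta3 replicate 1) all light-harvesting genes had median deviations of 0.60, 0.41 and 1.05, fatty acid synthesis genes -0.07, -0.08 and -0.15, and genes that fell most with light 0.34, 0.32 and 0.18.

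The deposited q-values called 8090 genes in WT light, 8262 in Na1 light and 8269 in Ta3 light. Of these 7942, 7987 and 7971 were also called here, 7743, 7987 and 7836 with the same sign. The deposited median log2 fold change was 0.492 in WT light and 0.508 in Ta3 light. For the lines in darkness 2264 (Na1) and 1985 (Ta3) genes were called in the deposited columns, 2081 and 1800 of them also here, and after blue light 4096 and 1976, of which 3483 and 1511 also here, all with the same sign.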
